A study of Arabidopsis thaliana with 9 samples.

How the data were processed

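The series holds RNA sequencing of 9 Arabidopsis thaliana Col-0 libraries: rosette leaves, wild-type callus and emf2 callus (allele emf2-1 per the file headers), with 3 biological replicates each. Per the labels, total RNA was polyA-selected, libraries were made with the TruSeq RNA V2 kit and 15 PCR cycles, and 4 libraries were loaded per lane of an Illumina HiSeq. The submitters' notes name FastQC, cutadapt and TopHat and the TAIR10 genome, without versions, order or roles, and the counter of reads is not stated. Per the file headers, the authors' deposited values are RPKM, mapped reads scaled by gene length and library, in 1 table per group that lists genes with a group mean above 1 RPKM. The lowest listed means were 1.00 in each table, and the group means in the tables equalled the means of the replicate columns.

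The plan of the analysis preferred read counts and named RPKM as the second option, and the deposited unit, RPKM, set which was used. The values were also used to recover the reads behind them. Ratios between libraries were whole-number ratios at a relative tolerance of 5e-13, and 18852 of 18861 listed genes (99.95%) gave whole reads in every library that lists them, with gene lengths that were whole within 1e-06 bases, against 20.0% in a decoy. The recovered reads per library were 39.7 to 54.4 M, with medians of 613 to 1398 reads per listed gene. The implied gene length equalled the gene span for 1207 of 16311 multi-exon genes and the union of exons for 53. Its median log2 ratio was −0.07 to the span and 0.41 to the exon union. The scale of the lengths and the multiple taken for each gene were set by the span. Closeness to the span is thus partly built in and cannot tell which length the authors used. The denominators of the deposited RPKM differ from the recovered reads by a factor of 0.663 in leaf, 1.23 in wild-type callus and 1.26 in emf2 callus (geometric means), and by 1.01 over all 9 libraries, so the deposited scaling is not that of library totals. Read depths speak to counting error only, and the interval of the share toward leaf treats genes as independent. Of the 18861 genes, 18843 matched the TAIR10.1 annotation, which gave coordinates and overlaps, and 18546 were protein coding.

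Values were analysed as log2(RPKM + 1) with R 4.3.3 and limma 3.58.1. A single fit with 1 coefficient per group used all libraries of the groups that list a gene, and the spread was moderated with a trend on the mean (eBayes). Contrasts were wild-type callus minus leaf, emf2 callus minus wild-type callus and emf2 callus minus leaf, each over the genes listed in both groups, with Benjamini-Hochberg adjustment within the contrast. A gene passed at an adjusted p under 0.05, two-sided, and a second count asked for at least 2-fold. Fold changes are on the scale of log2(RPKM + 1), which draws changes of genes near 1 RPKM toward 0. A gene listed in 1 of the compared groups was tested against the highest mean its absence allows, 1 RPKM, with the fitted spread and a separate Benjamini-Hochberg adjustment; this test was chosen after the tables were seen. Standard errors had a median of 0.18 log2 units in each contrast.

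Before the data were examined, 22 gene lists with 391 members (303 of them in a table), the contrasts, the thresholds and the rule for named genes were fixed. The lists were Polycomb components and H3K27 demethylases, floral organ identity, flowering time, embryo and seed maturation, photosynthesis, root stem cell and lateral root founder, differentiated root tissue, shoot meristem and shoot regeneration, leaf development and polarity, stomatal lineage with trichome and epidermis, vascular tissue, auxin response, auxin synthesis and transport, cytokinin response and breakdown, cell cycle, wound and callus induction, core hypoxia response, dark induced, heat shock, defence, flavonoid and anthocyanin, and reference genes. Lists with at least 5 tested members were tested with camera on the moderated statistics at a preset correlation of 0.01, adjusted over 45 tests. They were tested again with an estimated correlation, under which 0 lists passed in any contrast, against 4, 4 and 5 at the preset value. The second test was fitted on the libraries of the 2 compared groups alone, so more than the correlation differs between the tests. For auxin response in wild-type callus against leaf the estimate was 0.0104, near the preset value. Its unadjusted camera p was still 0.0213, against 0.000277 in the first test. The rule names EMF2, then the 8 largest rises and 8 largest falls among passing genes whose groups do not overlap and whose higher mean is at least 5 RPKM, then up to 4 passing members of each list with at least a 2-fold change, up to 30 genes per contrast. These rises and falls were ranked among genes listed in both groups. One gene that the rule names is not reported here. Other list members are named where their list is described, and genes absent from a table are named by their level.

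The test was tried on simulated data with known changes and the fitted spread of each gene, where it made 0 calls in the wrong direction and 5 of 78, 4 of 56 and 2 of 61 calls were of unchanged genes in the 3 contrasts. The noise was normal, independent between genes and equal in all groups, as the test itself assumes. These rates therefore do not cover shifts shared by many genes of a library. The share of emf2 changes that point back toward leaf was set beside 20 simulations of an unchanged emf2 group. Other settings planned at the start were a pseudocount of 0.1, quantile normalization, the replicate number as a block, a fit of the compared groups alone, an adjusted p under 0.01, and leaving out each library. Alternatives added later were library totals of the recovered reads as the scaling, a mean of at least 5 RPKM, limma-voom on the recovered reads, and leaving out leaf replicates 2 and 3. Tables, family tests (Fisher's exact test, one-sided) and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the main values.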

Results

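Polyadenylated RNA was sequenced from Arabidopsis thaliana Col-0 in 3 groups of 3 libraries each, which the labels call biological replicates. The groups were rosette leaves of wild-type plants, wild-type callus and callus of the emf2 mutant. EMF2 encodes a subunit of Polycomb Repressive Complex 2, which places the trimethyl mark on lysine 27 of histone H3 (H3K27me3) and keeps developmental genes silent. Callus, a mass of dividing cells in culture, was raised from cotyledons on Gamborg B5 medium with 2.2 µM of the auxin 2,4-D and 0.46 µM of the cytokinin kinetin, was moved to the dark and was analysed at 6 to 8 weeks. Leaves came from plants grown for 1 week on medium in continuous light and for 2 weeks on soil in long days. The values are RPKM (reads scaled by gene length and by library), and each table lists the genes whose group mean was above 1 RPKM. There were 16694 such genes in leaf, 16703 in wild-type callus and 16646 in emf2 callus, 18861 in any group and 14476 in all 3. A gene missing from a table therefore had a mean of at most 1 RPKM in that group. Positions are in the TAIR10 genome.

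The reads behind the values, recovered from the ratios between libraries, came to 42.1, 39.7 and 43.9 M (mega) reads in leaf replicates 1, 2 and 3, to 54.4, 51.2 and 42.0 M in wild-type callus, and to 47.5, 54.0 and 40.2 M in emf2 callus. At the median gene length, 1 RPKM stood for 54.2 to 159 reads, so counting error was small beside the spread between libraries. The p of single genes below measures that spread between these samples, while the p of a gene list compares its genes with the others. In simulated data with few changed genes the test recovered 29.8%, 27% and 20.7% of 2-fold changes, and 85.9%, 72.7% and 79.7% of 4-fold changes, for wild-type callus against leaf, emf2 against wild-type callus, and emf2 callus against leaf. The simulated noise was independent between genes, so shifts shared across a library are not covered.

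EMF2 itself (AT5G51230, chromosome 5, 20823644 to 20829644) was read in every library. Its level was 5.50, 6.07 and 29.6 RPKM in leaf, 7.43, 6.78 and 7.55 in wild-type callus, and 13.0, 15.5 and 16.3 in emf2 callus. The labels do not describe the lesion, so the transcript level cannot check the genotype. The first principal component of 14476 genes took 85.2% of the variance and parted leaf from callus, and the second took 5.32%. On the second component wild-type callus replicate 2 lay at 13.3, between the emf2 callus libraries (2.56, 20.3 and 24.0), while wild-type replicates 1 and 3 lay at −18.4 and −41.8. Stress genes set leaf libraries apart. The median of 9 heat shock genes was 75.3 RPKM in leaf replicate 2 against 1.34 and 1.94 in leaf replicates 1 and 3, and the median of 7 defence genes was 71.0 in leaf replicate 3 against 11.9 and 35.9 in replicates 1 and 2.

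**Figure D1:**
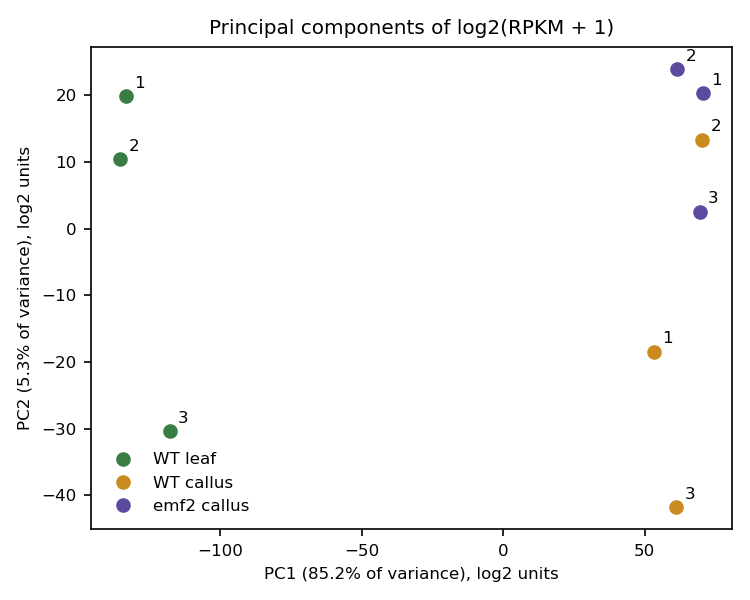
Scores of the 9 libraries on the first (85.2% of variance) and second (5.32%) principal components of log2(RPKM + 1), in log2 units, coloured by group and numbered by replicate. Leaf lies apart from both calli on the first axis, and wild-type callus replicate 2, at 13.3 on the second, lies among the emf2 callus libraries.

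**Figure D2:**
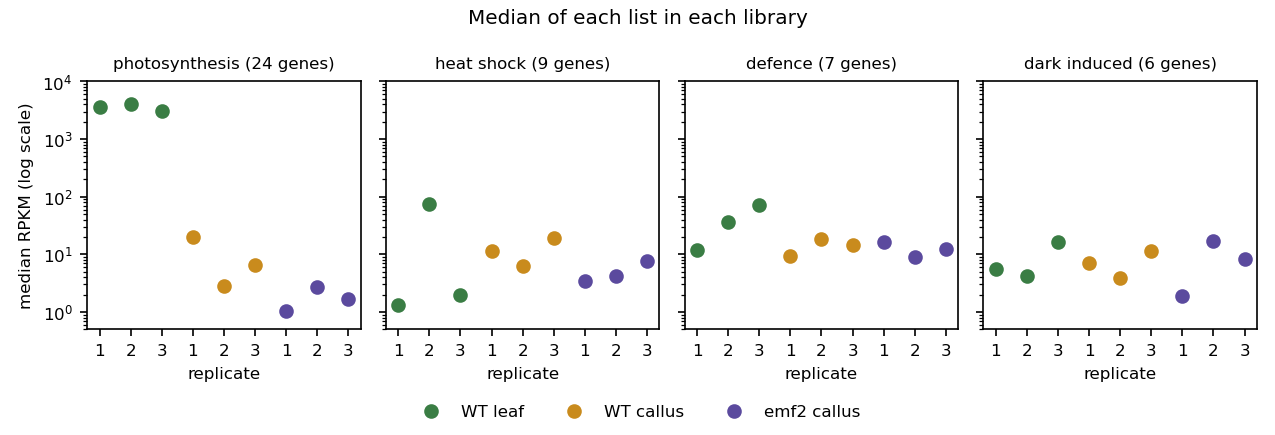
Median RPKM (log scale) in each library of the list members present in all 3 tables, for photosynthesis (24 genes), heat shock (9), defence (7) and dark-induced genes (6). Photosynthesis medians lie at 3101 to 4018 in leaf, 2.78 to 19.8 in wild-type callus and 1.03 to 2.71 in emf2 callus.

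Wild-type callus was compared with leaf to ask which genes mark the cultured tissue. Tissue, medium, light and age differ together in this comparison. Photosynthesis genes fell in callus, most tested genes of hypoxia, auxin response and the cell cycle rose, and most root stem cell genes were listed for callus alone. RBCS1A (AT1G67090), a small subunit of Rubisco, was at 22819 ± 5934 RPKM in leaf and 1.3 ± 1.67 in callus (SD, n = 3), a log2 fold change of −13.49 (SE 0.68, adjusted p = 1.43e-06). ADH1 (AT1G77120), the alcohol dehydrogenase of fermentation, was at 1390 ± 105 RPKM in callus and 3.74 ± 0.102 in leaf, a log2 fold change of 8.19 (SE 0.18, adjusted p = 2.77e-07), and 61 of its bases overlap another gene. EMF2 was at 7.25 ± 0.414 in callus and 13.7 ± 13.8 in leaf and did not pass (log2 fold change −0.44, adjusted p = 0.475). The lower value in callus rests on leaf replicate 3 (29.6 RPKM against 5.50 and 6.07), without which the log2 fold change was 0.28 (adjusted p = 0.0741). Under library-total scaling it was 0.33.

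With ADH1, the largest rises in callus among genes listed in both tissues were LTP2, a lipid transfer protein (1083 ± 274 against 2.95 ± 0.922 RPKM), ARD3, an acireductone dioxygenase (539 ± 256 against 2.6 ± 3.24), and the auxin-conjugating enzymes GH3.3 (996 ± 151 against 8.37 ± 11.3) and GH3.2 (261 ± 49.9 against 1.27 ± 1.70). PGB1, a hemoglobin of low-oxygen tissue (395 ± 135 against 2.78 ± 2.00), the lectin PBP1 (712 ± 227 against 6.14 ± 1.21) and the drought-induced DI21 (465 ± 196 against 3.6 ± 0.455) rose as well. Their log2 fold changes ran from 6.59 for DI21 to 8.10 for LTP2. The largest falls after RBCS1A among genes listed in both tissues were LHCB2.1, LHCB1.1, LHCB1.2 and LHB1B1 of the light-harvesting antenna, RCA (Rubisco activase), PSAO of photosystem I and AT2G25510, a transmembrane protein. LHCB1.1 was at 9829 ± 2533 RPKM in leaf and 10.5 ± 12.2 in callus, RCA at 8360 ± 2604 and 7.77 ± 5.61, and AT2G25510 at 2136 ± 805 and 1.27 ± 0.316. The naming rule requires that in each of these 16 genes the 3 callus libraries lie on the same side of all 3 leaf libraries. Among genes absent from the leaf table, OSM34 (osmotin) was at 837 ± 505 RPKM in callus and the lectin JAL33 at 468 ± 83.6. Among genes absent from the callus table, RBCS3B was at 8942 ± 1233 RPKM in leaf and the chloroplast aldolase FBA2 at 2772 ± 966. Against the 1 RPKM bound the log2 fold change of RBCS3B was −12.12, beyond that of LHCB2.1 (−10.86).

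Of 44 photosynthesis genes, all 34 listed in both tissues fell in callus, also when adjusted over the list alone, with a median log2 fold change of −9.03, and the 10 listed only for leaf passed against the 1 RPKM bound (list test, adjusted p = 4.52e-24, or adjusted p = 0.8 with an estimated correlation). In callus the same genes were highest in replicate 1, with a median of 19.8 RPKM for the 24 members in all tables against 2.78 and 6.42 in replicates 2 and 3. Of the core hypoxia genes listed in both, 5 rose, among them the sucrose synthase SUS1 (101 ± 10.1 against 20.5 ± 4.66 RPKM), and the stress gene SRO5 fell, counts that held when adjusted over the list alone, although the fall of SRO5 was lost under quantile normalization and under library-total scaling. Another 9 were listed for callus alone and passed, including the pyruvate decarboxylase PDC1 (341 ± 41.5) and the low-oxygen regulator LBD41 (204 ± 8.20). The hypoxia list was up (median log2 fold change 2.34, adjusted p = 3.6e-05, or adjusted p = 0.579 with an estimated correlation).

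Of 13 auxin response genes, 11 rose, 1 fell and 1 did not pass, the same when adjusted over the list alone, and IAA17, which did not pass, rose under both other scalings. GH3.5 went from 9.65 ± 8.75 to 326 ± 84.6 RPKM and the repressor gene IAA5 from 1.96 ± 0.153 to 54.4 ± 27, while IAA3 fell from 38.3 ± 18.8 to 4.66 ± 2.55. The list was up (median 2.87, adjusted p = 0.00139, or adjusted p = 0.579 with an estimated correlation). Another 4 members, such as IAA30 (41.4 ± 6.19), passed as listed for callus alone, and IAA6 passed as listed for leaf alone. Of 6 genes of auxin synthesis and transport, 2 rose, such as the efflux carrier PIN7 (95.5 ± 11.2 against 17.3 ± 8.68 RPKM), PIN4 fell and 3 did not pass, also when adjusted over the list alone (list adjusted p = 0.330). The fall of PIN4 was lost under library-total scaling.

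Of 24 cell cycle genes, 23 rose and CYCD3;2 fell, also when adjusted over the list alone, but the fall of CYCD3;2 was lost under both other scalings. The D-type cyclin CYCD3;3 rose from 3.23 ± 0.362 to 19.2 ± 2.18 RPKM, the replication helicase subunit MCM2 from 2.64 ± 0.857 to 13.1 ± 1.43 and the mitotic kinase CDKB1;1 from 1.00 ± 0.380 to 11.7 ± 1.54. The list was up (median 1.59, adjusted p = 1.97e-05, or adjusted p = 0.8 with an estimated correlation). Another 10 of 11 members listed for callus alone passed, such as CYCB1;1 (4.60 ± 1.12), and CYCD1;1, listed for leaf alone, did not.

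Root stem cell and lateral root founder genes were mostly absent from leaf: 14 were listed for callus alone and 13 of them passed. WOX11, a founder-cell gene, was at 87.6 ± 12.1 RPKM, the quiescent centre gene WOX5 at 34.3 ± 13.1 and PLT3 at 63.6 ± 15.7. Of 6 members listed in both, PLT5 (13.6 ± 1.48 against 1.13 ± 0.241), SHR and ARF19 rose, SCR and ARF7 fell and ALF4 did not pass, also when adjusted over the list alone (list adjusted p = 0.362). The falls of SCR and ARF7 were lost under quantile normalization, and under library-total scaling ARF7 and ALF4 rose and SCR did not pass. Markers of differentiated root were listed for callus alone in 6 cases, of which RHD6, MYB36, PYK10 (392 ± 157) and NAI2 (112 ± 28.7) passed, and PHO1 passed as listed for leaf alone. Of 5 genes of embryo and seed maturation, the only member in both tables, WRI1, rose. With 1 tested member, adjusting over the list alone is no adjustment. BBM, an embryo and regeneration factor (15.3 ± 5.65), AGL15 (8.49 ± 1.13) and ABI5 passed as listed for callus alone, and LEC1 (2.31 ± 1.5) did not.

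Shoot and leaf regulators moved in both directions. The 2 shoot meristem members in both tables, REV (17.7 ± 1.3 against 6.30 ± 1.74) and PNY, rose, also when adjusted over the list alone. Of 7 listed for callus alone 6 passed, such as RAP2.6L (82.2 ± 12.5), while STM (2.51 ± 1.67) did not, and the receptor gene CLV1 (27.8 ± 1.57) and ATH1 passed as listed for leaf alone. Of 5 leaf development genes, the polarity factors PHV (51.7 ± 15.4 against 7.23 ± 0.111) and PHB rose, AS1 and TCP2 fell and TCP24 did not pass, also when adjusted over the list alone. The median of these 5 was −0.20 and their mean 0.31 with a test pointing up (adjusted p = 0.736). Under quantile normalization and library-total scaling the median turned to 0.01 and 0.57 and the fall of AS1 was lost, and TCP24 rose under library-total scaling. Of 9 members listed for leaf alone 6 passed, such as TCP4 (19.1 ± 4.55). Of the stomatal and epidermal genes, FDH, an epidermal wax enzyme, fell (23.8 ± 14.2 against 124 ± 21.9), PDF1 did not pass, with the same counts adjusted over the list alone, and 8 of 8 listed for leaf alone passed, such as the guard cell channel KAT1 (9.20 ± 1.39). Of 9 vascular genes, the procambium regulators ATHB8 (30.8 ± 9.42 against 4.70 ± 0.868), WOX4 and PXY rose, SEOR1, XCP2 and CESA4 fell and 3 did not pass, also when adjusted over the list alone, and 6 of 7 listed for leaf alone passed, such as the phloem sucrose carrier SUC2 (185 ± 24.8). The vascular median was −0.74 and mean −0.45 with a test pointing up (adjusted p = 0.922), and the mean turned to 0.26 under library-total scaling.

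The Polycomb and H3K27 demethylase list held 18 genes in both tissues, of which 8 rose, 1 fell and 9 did not pass, also when adjusted over the list alone (median log2 fold change 0.34, list adjusted p = 0.155). Under quantile normalization 13 rose (median 0.62) and under library-total scaling 15 (median 1.13). RING1B rose from 1.17 ± 0.438 to 12.8 ± 5.03 RPKM, the methyltransferase CLF from 3.00 ± 0.614 to 8.31 ± 0.837 and MSI1 from 11.9 ± 0.308 to 33.1 ± 2.9. The demethylase JMJ13 fell from 18.3 ± 4.80 to 2.80 ± 0.164, and 268 of its bases overlap another gene. Among 3 flowering time genes, GI rose and SVP (2.88 ± 0.783 against 18.1 ± 0.514) and FLM fell, also when adjusted over the list alone, with a median of −0.38 that became 0.39 under library-total scaling, and FLM did not pass under either other scaling. FD passed as listed for callus alone and SOC1 (14.3 ± 9.19) and AGL24 as listed for leaf alone, while AGL42, FT and CO did not. The floral organ genes had no member in both tables, and PI (22.3 ± 3.00 in callus) and SEP4 (10.0 ± 4.28 in leaf) passed as listed for 1 tissue.

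Of 8 cytokinin genes, the oxidase CKX5 rose (9.35 ± 1.84 against 2.35 ± 1.48, with 1125 bases shared with other genes), ARR4, ARR5, ARR7 and CKX6 fell and 3 did not pass, also when adjusted over the list alone. Their median of −0.49 (adjusted p = 0.881) turned to 0.11 under quantile normalization and 0.35 under library-total scaling, and the falls of ARR4 and ARR5 were lost. Under library-total scaling the fall of CKX6 was lost too, and ARR8 and ARR9 rose. ARR3 and CKX3 passed as listed for callus alone, and 4 members did as listed for leaf alone. Of 4 wound and callus induction genes, WIND2 (43.4 ± 9.42 against 292 ± 56.3), ABR1 and PAT1 fell and WIND1 did not pass, also when adjusted over the list alone. WIND1 rose under both other scalings and the fall of PAT1 was lost under library-total scaling. WIND3 (160 ± 55.7) and ERF115 (24.8 ± 12.3) passed as listed for callus alone and ERF109 (622 ± 119) as listed for leaf alone.

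Among 7 defence genes, EDS5 rose, 5 fell and PAD3 did not pass, also when adjusted over the list alone (median −1.81, adjusted p = 0.707). The fall of ICS1 was lost under quantile normalization, and those of ICS1, CYP71A13 and PAD4 under library-total scaling, where 2 fell and the median was −0.94. EDS1, a regulator of immunity, went from 65.6 ± 5.03 to 18.1 ± 3.39, while PR1 was at 1144 RPKM in leaf replicate 3 against 12.7 and 72.7 in leaf replicates 1 and 2. PR2 and PR5 passed as listed for leaf alone and 2 others did not. UGT78D2, the only flavonoid gene in both tables, fell (4.94 ± 1.83 against 71.7 ± 48.5), and CHS and CHI but not 2 others passed as listed for leaf alone. None of the 6 dark-induced genes (median 0.08, mean −0.22, adjusted p = 0.922) and none of the 9 heat shock genes (median 0.21, adjusted p = 0.881) passed in limma, over all genes or adjusted over the list alone, though DIN3 rose under library-total scaling. DIN2 (94.7 ± 29.8) passed as listed for callus alone and HSP22 did not. Of 7 reference genes, TIP41 rose and ACT2 fell over all genes, ACT2 alone passed when adjusted over the list alone (78.9 ± 13.1 against 572 ± 158), and the list median of −0.05 (adjusted p = 0.881) became 0.22 under quantile normalization and 0.76 under library-total scaling, where 6 rose.

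In limma, 9672 of 14780 genes listed in both tissues passed, 4969 higher and 4703 lower in callus, and 5494 of them changed at least 2-fold (2207 higher, 3287 lower). The 2-fold split turned round under quantile normalization (3580 higher, 2537 lower) and library-total scaling (6166 higher, 1957 lower). A further 1119 of 1923 genes listed for callus alone and 1438 of 1914 listed for leaf alone passed against the bound. The 1 RPKM minimum is on the deposited scale, so which genes are listed for 1 tissue depends on that scaling. Calls against the bound were not repeated under quantile normalization or library-total scaling. Quantile normalization moved the median of all genes by 0.29 log2 units toward callus and library-total scaling by 0.79, with 65.3% and 77.7% of the passing genes higher in callus in place of 51.4%.

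**Figure D3:**
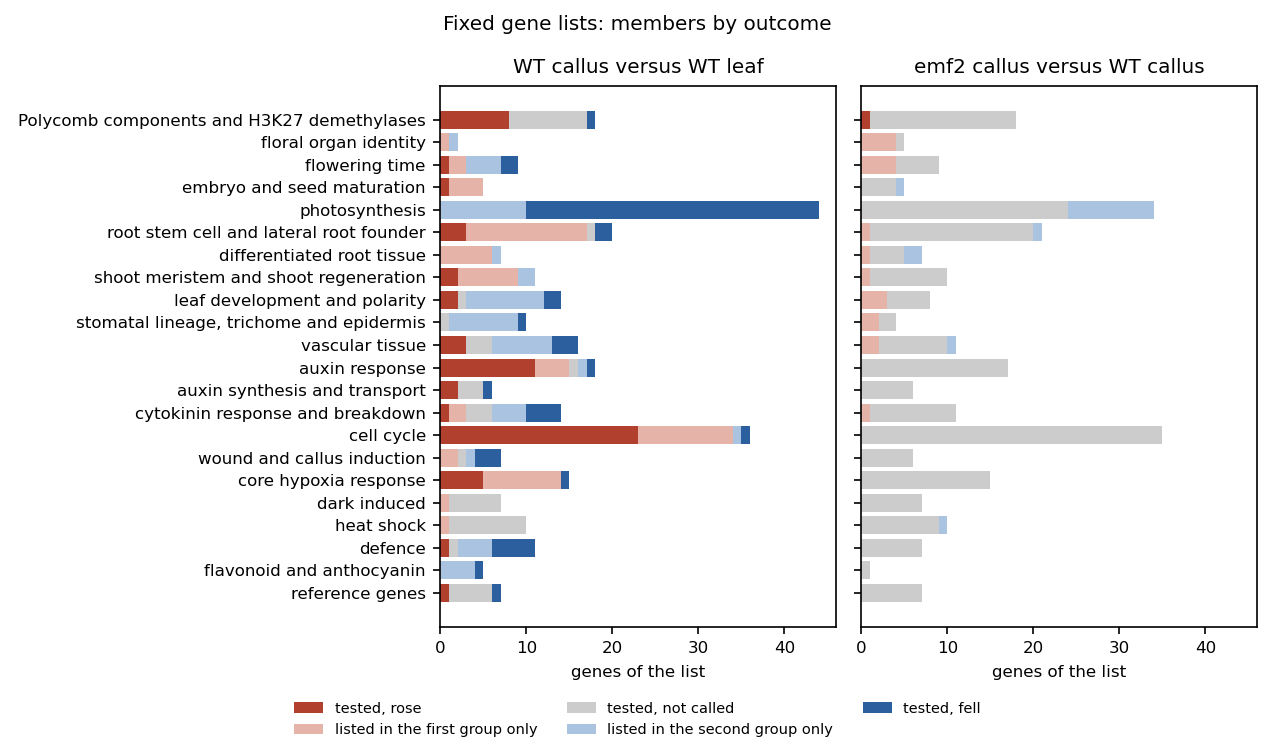
Number of members of each fixed gene list that rose, fell or did not pass in limma (tested in both tables), or that were listed for 1 of the 2 groups, for wild-type callus against leaf and emf2 callus against wild-type callus. In callus against leaf all 34 tested photosynthesis genes fell and 23 of 24 cell cycle genes rose, while the medians of the cytokinin, leaf development and reference lists changed sign under other scalings of the libraries.

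Callus of the emf2 mutant was compared with wild-type callus to ask which genes change in culture when this Polycomb subunit gene is mutated. Few genes passed, among them EMF1 and AGL44, which rose, and TEM1 and TOE2, which fell. EMF1 (AT5G11530, chromosome 5, 3695792 to 3701549), which acts with Polycomb in repression, rose from 8.36 ± 1.2 to 66.0 ± 4.74 RPKM (SD, n = 3), a log2 fold change of 2.84 (SE 0.12, adjusted p = 0.000153), with 60.5, 69.0 and 68.4 in the emf2 libraries. AGL44 (AT2G14210), a MADS-box gene of root nitrate response, rose from 3.75 ± 1.14 to 42.5 ± 3.83 (log2 fold change 3.22, SE 0.20, adjusted p = 0.00801). The MADS-box genes SHP1 (8.04 ± 1.73), SEP2 (8.44 ± 1.97) and TT16 (15.8 ± 1.11) were absent from the wild-type callus table and passed against the bound (adjusted p = 0.00948, 0.0103 and 0.00233). The transcription factors TEM1 (32.5 ± 2.77 to 9.81 ± 2.41) and TOE2 (9.90 ± 2.11 to 2.86 ± 0.244) fell. EMF2 was at 14.9 ± 1.70 against 7.25 ± 0.414, which did not pass (log2 fold change 0.95, SE 0.52, adjusted p = 0.656). The SE of EMF2 is shared by all 3 groups and carries the spread of leaf replicate 3. Without that library EMF2 rose (SE 0.11, adjusted p = 0.0296), and with the calli fitted alone it just missed (SE 0.11, adjusted p = 0.0580).

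The other large rises were AT2G25330 of the TRAF-like family (16.8 ± 0.708 against 1.03 ± 0.0987 RPKM), HAP8 (33.2 ± 1.92 against 4.73 ± 1.49), the F-box gene AT5G60610 (11 ± 0.730 against 1.22 ± 0.192), AT5G05040 of the cystatin and monellin superfamily (17.41 ± 1.04 against 2.43 ± 0.0457), the lipase GLIP3 (9.37 ± 0.268 against 1.48 ± 0.604) and AT3G60520, a zinc ion-binding protein (14.6 ± 4.01 against 3.01 ± 0.900). The other falls were the VQ motif gene AT1G80450 (2.68 ± 0.551 against 16.5 ± 3.84), ATPMEPCRB (1.04 ± 0.136 against 5.81 ± 1.42) and the helicase gene AT2G47680 (3.26 ± 0.205 against 11.7 ± 0.685). As the naming rule requires, in each of these genes the 3 emf2 libraries lay on the same side of the 3 wild-type libraries. AGL15, a MADS-box gene linked to embryogenesis, was at 8.49 ± 1.13 RPKM in wild-type callus and absent from the emf2 table (adjusted p = 0.00514). Among genes absent from the wild-type table, AT5G17090 of the cystatin and monellin superfamily was highest (87.4 ± 2.58), and the growth regulator TCP1 was at 18.0 ± 2.96.

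**Figure D4:**
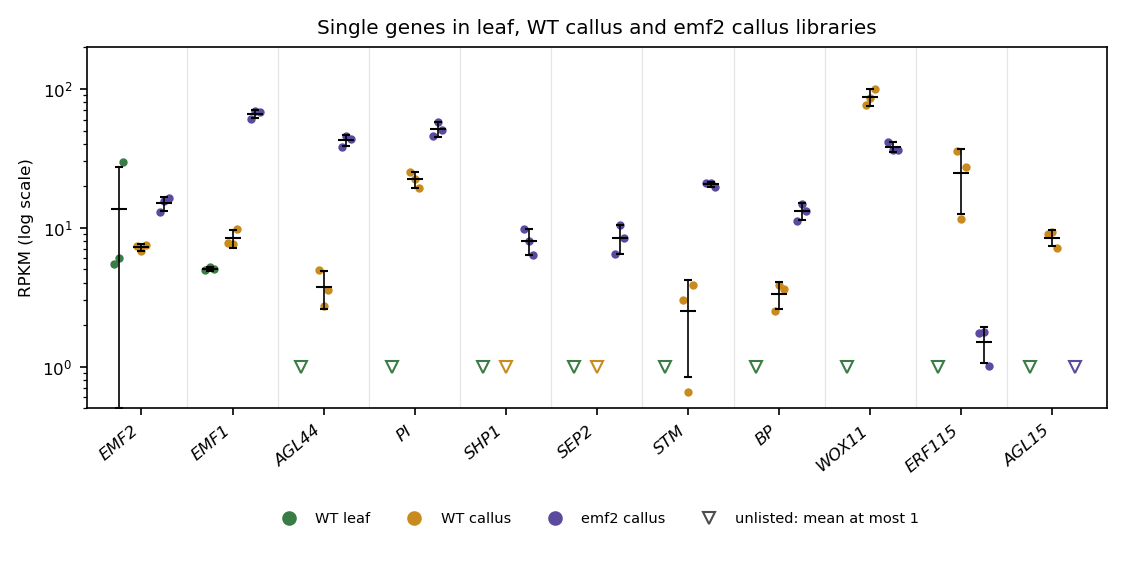
RPKM (log scale) of single genes in each library, with the mean and SD of each group (n = 3), and open triangles where a gene is missing from a group's table and its mean is at most 1. EMF1 lies at 60.5 to 69.0 in emf2 callus against 7.60 to 9.74 in wild-type callus, and the lower SD bar of EMF2 in leaf (13.7 ± 13.8) stops at the foot of the axis.

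Of 18 Polycomb and demethylase genes, EMF1 rose and 17 did not pass, also when adjusted over the list alone. The list test pointed up (adjusted p = 0.00122, or adjusted p = 0.844 with an estimated correlation) at a median log2 fold change of 0.01 and a mean of 0.20. EMF1 (log2 fold change 2.84) draws both the mean and the test up, and the list was not tested without it. PI, the floral organ gene in both tables, was at 51.3 ± 6.01 against 22.3 ± 3.00 (adjusted p = 0.0726) and rose when adjusted over the list alone. With 1 tested member that is no adjustment. SEP2 and SHP1 passed as listed for emf2 callus alone, while AG (1.77, 1.63 and 1.15 RPKM) and STK (1.5 ± 0.147) did not. None of 5 flowering time genes passed over all genes, and SVP (5.46 ± 0.638 against 2.88 ± 0.783) and FLM rose when adjusted over the list alone. FLC, at 2.69, 4.51 and 1.87 RPKM, and MAF4, MAF5 and CO, listed for emf2 callus alone, did not pass. The flowering time list was up (median 0.44, adjusted p = 0.0342, or adjusted p = 0.812 with an estimated correlation). It was not up without emf2 replicate 2 (0.110), wild-type callus replicate 2 (0.130), wild-type callus replicate 3 (0.132) or leaf replicate 3 (0.0720), nor under library-total scaling (0.0541), with the replicate number as a block (0.102), with the 2 groups fitted alone (0.0572) or without leaf replicates 2 and 3 (0.0605). At a mean of at least 5 RPKM too few members were left for a test.

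All 24 photosynthesis genes in both tables missed the threshold, over all genes and adjusted over the list alone, and so did 10 listed for wild-type callus alone. As a list they were down (median −1.41, adjusted p = 7.74e-09, or adjusted p = 0.812 with an estimated correlation). Their library medians were 19.8, 2.78 and 6.42 RPKM in wild-type callus and 1.03, 2.71 and 1.69 in emf2 callus, and without wild-type callus replicate 1 the median log2 fold change was −0.62. The 6 wound and callus induction genes were down as a list (median −0.25, adjusted p = 0.0376, or adjusted p = 0.8 with an estimated correlation). The list did not pass without wild-type callus replicate 1 (0.130), wild-type callus replicate 3 (0.0658), emf2 replicate 1 (0.118) or leaf replicate 3 (0.0720), nor under quantile normalization (0.0536), with the replicate number as a block (0.0870), with the 2 groups fitted alone (0.0940), at a mean of at least 5 RPKM (0.0583), in limma-voom (0.290) or without leaf replicates 2 and 3 (0.0907). None of them passed over all genes, and ERF115, a gene of wound repair, fell when adjusted over the list alone, from 24.8 ± 12.3 to 1.5 ± 0.431.

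None of 9 shoot meristem genes passed over all genes. When adjusted over the list alone, the meristem homeobox genes STM (2.51 ± 1.67 to 20.6 ± 0.769) and BP (3.33 ± 0.731 to 13.1 ± 1.81) rose and CUC2, ESR1 and LAS fell. The list median was −0.29, the mean 0.01 and the test up (adjusted p = 0.683), and PNF, listed for emf2 callus alone, did not pass. Of 19 root stem cell genes none passed over all genes, and when adjusted over the list alone WOX11 (87.6 ± 12.1 to 38.0 ± 3.19) and PLT5 (13.6 ± 1.48 to 5.01 ± 1.16) fell and SCR (11 ± 2.57 to 27.9 ± 3.79) rose (list median 0.09, adjusted p = 0.867). LBD29 and FEZ, each listed for 1 callus, did not pass. PLT5 fell and BP rose over all genes under quantile normalization and library-total scaling, and TCP2 rose and ERF115 fell under quantile normalization. Of 5 leaf development genes none passed over all genes, PHB and TCP2 rose and TCP24 fell when adjusted over the list alone (median 0.08, adjusted p = 0.249, but 0.0410 without emf2 replicate 3 and 4.59e-05 with the replicate number as a block), and of 3 listed for emf2 callus alone YAB2 passed (3.2 ± 0.247). The epidermal genes PDF1 (17.0 ± 12.7 against 1.86 ± 1.58) and FDH (67.2 ± 14.7 against 23.8 ± 14.2) rose when adjusted over the list alone but not over all genes, and ATML1 and PDF2, listed for emf2 callus alone, did not pass. With 2 tested epidermal members, adjusting over the list alone is little adjustment. Of 8 vascular genes ACL5 (107 ± 34.8 against 15.7 ± 13.8) rose when adjusted over the list alone (median 0.36, adjusted p = 0.312, but 0.0494 without wild-type callus replicate 1), and the 3 listed for 1 callus did not pass.

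In the remaining lists no member passed in limma over all genes or adjusted over the list alone. These were 17 auxin response genes (median −0.34, adjusted p = 0.0737), 6 of auxin synthesis and transport (0.24, 0.433), 10 of cytokinin (0.15, 0.370), 35 of the cell cycle (0.15, 0.555), 15 of hypoxia (−0.06, 0.602), 7 dark-induced (−0.32, 0.602), 9 of heat shock (−0.36, 0.507), 7 of defence (0.15, 0.922) and 7 reference genes (−0.13, 0.507). The mean of the hypoxia list turned to 0.01 under quantile normalization. Some of these list tests passed in another setting: auxin response under library-total scaling (0.0448), without wild-type callus replicate 1 (0.00455) or emf2 replicate 1 (0.0205), the cell cycle without wild-type callus replicate 2 (0.0174) and the dark-induced list without emf2 replicate 2 (0.00794). Too few members stood in both tables for a list test of 4 embryo genes (median 0.03, mean −0.01, and −0.02 for the median under quantile normalization), 4 markers of differentiated root (−0.31) and the flavonoid gene UGT78D2 (−0.25). GH3.3, for example, was at 739 ± 101 against 996 ± 151 RPKM, ADH1 at 948 ± 205 against 1390 ± 105, and UBQ10 at 1089 ± 141 against 1203 ± 168. Apart from AGL15, no gene of these lists that stood in 1 callus table passed against the bound.

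In limma, 16 of 16185 genes passed, 11 higher and 5 lower in emf2 callus, each by at least 2-fold, and 1457 had an unadjusted p under 0.05. Beside the 8 rises named by the rule, AT3G48185, AT4G00390 and AT5G56240 rose and are named here because the count is small, after their values were seen. These 3 genes did not pass without wild-type callus replicate 1 or any of the emf2 libraries, and their other losses are not listed below. A further 52 of 461 genes listed for emf2 callus alone and 9 of 518 listed for wild-type callus alone passed against the bound. The count of 16 depended on single libraries: it was 7 without wild-type callus replicate 1 and 121 without wild-type callus replicate 2, 4, 3 and 6 without emf2 replicates 1, 2 and 3, and 62 without leaf replicate 3, which enters through the shared spread. The 61 genes of 1 table became 36 without wild-type callus replicate 1 and 24, 32 and 33 without emf2 replicates 1, 2 and 3. Of the passing genes 68.8% were higher in emf2 callus, a share that was 42.1% without wild-type callus replicate 2, 50% without leaf replicate 3, 49.1% at a mean of at least 5 RPKM, 48.1% under quantile normalization and 51.5% under library-total scaling. EMF1, AT2G25330 and AT5G05040 passed without any 1 library. AT5G60610 did not pass without emf2 replicate 2, AGL44 and ATPMEPCRB without any of the emf2 libraries, TEM1 without wild-type callus replicate 1 or emf2 replicates 1 or 2, and HAP8, GLIP3, TOE2, AT1G80450, AT2G47680 and AT3G60520 without wild-type callus replicate 1 or any of the emf2 libraries. AT1G80450, AT2G47680 and AT3G60520 also did not pass without wild-type callus replicate 3 or leaf replicate 2, nor AT3G60520 without leaf replicate 1. Further calls were lost at a pseudocount of 0.1 (GLIP3, AT2G47680), with the replicate number as a block (GLIP3, AT3G60520), with the calli fitted alone (TEM1, TOE2, AT3G60520) and in limma-voom (TOE2, AT1G80450, ATPMEPCRB, AT3G60520).

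The remaining pair, emf2 callus against leaf, shares its libraries with the comparisons above. Relative to leaf, the tested photosynthesis genes fell in emf2 callus, most tested genes of hypoxia, auxin response and the cell cycle rose, and EMF1 rose. RBCS1A was at 1.69 ± 2.49 RPKM against 22819 ± 5934 in leaf (SD, n = 3), a log2 fold change of −13.40 (adjusted p = 1.4e-06), and EMF1 at 66.0 ± 4.74 against 5.06 ± 0.171 (log2 fold change 3.46, adjusted p = 3.96e-07). EMF2 did not pass (log2 fold change 0.50, adjusted p = 0.417), but it rose without leaf replicate 3 (1.23) and under library-total scaling (1.33). The largest rises among genes in both tables were LTP2 (1665 ± 416 against 2.95 ± 0.922), ARD3, ADH1 (948 ± 205 against 3.74 ± 0.102), PBP1, GH3.3, GH3.2, the trypsin inhibitor KTI1 (267 ± 79.5 against 2.49 ± 3.48) and the lectin JAL34, which shares 631 bases with a neighbour. Besides RBCS1A, the largest falls among genes in both tables were the antenna genes LHCB1.1, LHCB1.3 (6.94 ± 4.90 against 23374 ± 5140), LHB1B2 and LHCB3, the plastocyanin gene PETE2, and PSBR and PSAG of the photosystems. LHB1B2 and PSAG share 1144 and 479 bases with neighbours.

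All 24 photosynthesis genes in both tables fell (median −10.24, adjusted p = 8.42e-22, or adjusted p = 0.579 with an estimated correlation), also when adjusted over the list alone, and 20 listed for leaf alone passed. Of 24 cell cycle genes 23 rose (median 1.70, adjusted p = 1.01e-05, or adjusted p = 0.8 with an estimated correlation), such as CYCD3;3 (16.5 ± 1.75 against 3.23 ± 0.362). Of 13 auxin response genes 10 rose and IAA3 fell (median 2.47, adjusted p = 0.00384, or adjusted p = 0.579 with an estimated correlation), though the fall of IAA3 was lost under library-total scaling. Of 6 hypoxia genes 5 rose and SRO5 fell (median 2.87, adjusted p = 6.46e-05, or adjusted p = 0.579 with an estimated correlation), and 9 listed for emf2 callus alone passed, but the fall of SRO5 was lost under both other scalings. Of 18 Polycomb genes 10 rose and JMJ13 fell, and the list was up (median 0.46, adjusted p = 0.0299, or adjusted p = 0.579 with an estimated correlation), but not without leaf replicate 3 (0.0720) or leaf replicates 2 and 3 (0.0842). Under library-total scaling 17 of the 18 rose (median 1.3). The counts of these 5 lists were the same when adjusted over the list alone.

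Lists without a passing test in this pair kept members that passed singly. Of root stem cell genes, PLT5, SHR and ARF19 (24.0 ± 4.32 against 6.13 ± 0.227) rose and 13 of 14 listed for emf2 callus alone passed, such as WOX5 (52.7 ± 13.7). Of leaf development genes, PHB and PHV (46.9 ± 2.43 against 7.23 ± 0.111) rose and AS1, YAB3, TCP10 and TCP24 fell, with a median of −0.57 that turned to 0.26 under library-total scaling. Of epidermal genes, PDF1 rose and ATML1 and PDF2 (2.26 ± 0.382 against 14.1 ± 4.50) fell, with a mean of −0.53 that turned to 0.26 under library-total scaling. Of vascular genes, ATHB8, PXY and ACL5 rose and XCP1, XCP2 and CESA4 fell, with a median of −0.25 against a test pointing up (adjusted p = 0.730) and a median of 0.34 under library-total scaling, and TMO5 fell as well when adjusted over the list alone. Of flowering time genes, GI rose, SVP fell (5.46 ± 0.638 against 18.1 ± 0.514) and all 5 listed for emf2 callus alone passed, FLC among them, with a median of −0.14 that turned to 0.01 under quantile normalization and 0.51 under library-total scaling. PIN7 (112 ± 19.3 against 17.3 ± 8.68), CKX5, REV, EDS5 and WRI1 rose, and ARR5, ARR7, CKX6, WIND2 (35.9 ± 4.73 against 292 ± 56.3), ABR1, PAT1, EDS1 (11.7 ± 4.37 against 65.6 ± 5.03), PR1, PAD4, UGT78D2 and ACT2 fell. Of the falls in this paragraph, those of AS1, XCP1, ARR5 and PAD4 were lost under both other scalings, and those of TCP24, CESA4, CKX6 and PAT1 under library-total scaling. More genes rose under library-total scaling in the root stem cell (6 in place of 3), cytokinin (5 in place of 1), auxin synthesis and transport (4 in place of 2) and reference lists (6 in place of 0). PI, SEP2 and SHP1 passed as listed for emf2 callus alone and SEP4 as listed for leaf alone. No dark-induced or heat shock gene in both tables passed in limma, with medians of −0.15 and −0.26 against tests pointing up (adjusted p = 0.922 for each), and these medians and those of the cytokinin (−0.22) and reference (−0.15) lists turned positive under library-total scaling, where DIN3 rose, and, heat shock apart, under quantile normalization.

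In limma, 9595 of 14693 genes passed, 5004 higher and 4591 lower in emf2 callus, and 5367 changed at least 2-fold (2171 higher, 3196 lower). Another 1243 of 1953 genes listed for emf2 callus alone and 1522 of 2001 listed for leaf alone passed against the bound. These calls too rest on the deposited scale and were not repeated under the other scalings. Quantile normalization moved the median of all genes by 0.30 toward callus and library-total scaling by 0.83, with 66.0% and 78.8% of passing genes higher in place of 52.2%, and the 2-fold split turned round to 3592 higher and 2463 lower under quantile normalization and to 6443 higher and 1884 lower (8327 in all) under library-total scaling.

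The last comparison asked whether genes that part callus from leaf are also those that move in emf2 callus. Of 9459 genes that passed between wild-type callus and leaf, 5066 (53.6%, exact 95% confidence interval 52.5 to 54.6, which treats genes as independent) had an emf2 change that pointed back toward leaf. Because both comparisons share the wild-type callus libraries, 20 simulations with an unchanged emf2 group gave a mean of 53.7% (53.0 to 54.6), a range that held the share. Leaving out single libraries moved the share by more than this range. A place inside or outside the simulated range therefore cannot decide whether emf2 callus is unchanged along this difference. Other measures lay outside the simulated range: over the 14476 genes in all tables the covariance of the log2 fold changes of both comparisons was −0.000509 against −0.0413 to −0.0271 in the simulations, and their correlation −0.000869 against −0.0958 to −0.0648. Both measures weigh genes with large changes most. The 24 photosynthesis genes in both callus tables were lower in callus than in leaf and, as a list, lower still in emf2 callus (median −1.41). Their levels in callus were highest in wild-type replicate 1, and how much of the gap they carry was not tested. The simulated groups made 0 calls between the calli. TOE2 went from 2.20 ± 0.164 RPKM in leaf to 9.90 ± 2.11 in wild-type callus and back to 2.86 ± 0.244 in emf2 callus, while TEM1 went from 54.7 ± 5.26 to 32.5 ± 2.77 and on to 9.81 ± 2.41. Of genes higher in callus than in leaf, 3 were lower and 3 higher in emf2 callus, against 1.71 and 2.06 in independent lists, and of genes lower in callus 2 were higher and 2 lower, against 1.86 and 1.55. The share was 50.6% under quantile normalization and 47.4%, below even, under library-total scaling.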

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

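Tests and settings chosen only after the results were seen were library-total scaling, the minimum mean of 5 RPKM, limma-voom, the omission of leaf replicates 2 and 3, every test of genes in 1 table, and all but the planned settings of the share toward leaf. The counts of wild-type callus against leaf and of emf2 callus against leaf stayed within 1.5 times of 9672 and 9595 in every setting run (with leaf replicate 1 alone the callus libraries supply the spread), apart from the 2-fold count of emf2 callus against leaf under library-total scaling (8327 against 5367), and 1185 of 1244 values of named genes kept direction and side, with 55 weaker, 4 stronger and 0 reversed. Most named genes were picked for large changes, which seldom reverse. Among all passing genes of these 2 comparisons, the sign turned for 980 and 1047 under library-total scaling. Under quantile normalization it turned for 216 and 282. The count of emf2 against wild-type callus was 16 (16 at 2-fold), and became 52 (48) under quantile normalization, 33 (33) under library-total scaling, 57 (53) at a mean of at least 5 RPKM, 7 (7) at an adjusted p under 0.01, and 3 to 121 (3 to 119) with 1 library left out. All 16 genes were kept under quantile normalization, library-total scaling, the minimum mean and without wild-type callus replicate 2. Genes of 1 table between the calli fell from 61 to 32 at the stricter p, were 24 to 73 with 1 library left out, and without leaf replicates 2 and 3, with 1 leaf library left, the counts of 1 table against leaf were 406 (2557 in full) and 533 (2765), where fewer samples and a higher bound act by construction. With an estimated correlation, in a fit of the 2 compared groups alone, 0 of the 4, 4 and 5 list tests passed. With genes of 1 table at their bound 9, 7 and 11 did. For emf2 against wild-type callus 2 list tests passed with the 2 groups alone and at the minimum mean and without leaf replicates 2 and 3, and 2 to 5 with 1 library left out. The share toward leaf was 53.6%, and 50.6% under quantile normalization, 47.4% (reversed) under library-total scaling, 50.3% to 57.6% with 1 library left out, and with the wild-type callus libraries divided between the contrasts in 6 ways 56.5%, 45.1% (reversed), 42.8% (reversed), 56.7%, 52.9% and 50.2%. For these changes, unless stated, the cause was not tested. With the replicate number as a block 9790, 24 and 9770 genes passed. Libraries of the same number were not more alike by rule (correlations −0.21 to 0.61 in 9 pairs, −0.50 to 0.33 in 18 others), though the highest correlation was in a same-number pair. The ranges overlap and the pairs share libraries, so whether the numbers pair the libraries cannot be told. The block left residual freedom for 1926, 521 and 2013 genes of 1 table, those that the remaining group lists as well, of which 1349, 6 and 1446 passed with it and 1262, 13 and 1390 without it, so fewer genes tested act by construction on these counts. The planned count-based tests were not run because the unit is RPKM, and an analysis without the 1 RPKM minimum was not possible because the tables apply it. Genes at or under 1 RPKM are missing from the tables, and 1 RPKM is 54.2 to 159 reads at the median length. Of the 10 ways to split each pair of groups, the real one gave 8832, 20 and 9409 genes in fits of the 6 libraries and the highest other 0. Only the real split itself reached its count, and 10 splits are too few for a share under 0.05.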

Other observations

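The tests below were chosen only after the results were seen, except those of the genes beside EMF2 and of variants linked to the emf2 lesion. Gene families named in the annotation recur among the 63 genes higher in emf2 callus (11 in both tables, 52 in the emf2 table alone). MADS-box genes, transcription factors of flowering and seed development among other roles, made up 8 of the 63 and 31 of the 16646 genes of the emf2 table (one-sided Fisher's exact test, adjusted p = 1.37e-12 over 7 family tests). Chosen after their values were seen, they were AGL14, AGL17, AGL44, AGL71, AGL72, SEP2, SHP1 and TT16. Within the 461 genes of the emf2 table that are absent from wild-type callus, 7 of 14 MADS-box genes passed against 52 of all (adjusted p = 0.000406). F-box genes, which code for parts of ubiquitin ligases, made up 10 of the 63 and 181 of the background (adjusted p = 4.89e-09), and 9 of 21 among the 461 (adjusted p = 0.000268). Cystatin and monellin genes made up 3 of the 63 and 15 of the background (adjusted p = 5.31e-05), but 2 of 4 among the 461 (adjusted p = 0.0753), so whether they pass more often than other genes absent from wild-type callus stays open. These families were noticed in the same data they were tested on, and members of a family can share reads.

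Wild-type callus replicate 2 lay close to the emf2 callus libraries: over the 121 genes that pass without it, its median position on the step from the other wild-type libraries (0) to emf2 callus (1) was 0.538 (quartiles 0.292 and 0.802). The tables argue against emf2 callus RNA mixed into the library, as a single mixture would give genes of both directions the same linear share of the step, and its median share was 0.311 in the 51 genes higher in emf2 callus (quartiles 0.0866 and 0.437) and 0.765 in the 70 lower (quartiles 0.576 and 0.931). They also argue against an emf2 library with a wrong label: replicate 2 lay outside the emf2 libraries on the wild-type side in 101 of the 121 genes, with EMF1 at 7.60 RPKM against 60.5 to 69.0. Over genes with an unadjusted p under 0.001 when replicate 2 and 1 emf2 library were left out (107, 123 and 157 genes), its median position was 0.544, 0.568 and 0.633, and that of the omitted emf2 library 0.956, 0.990 and 0.814 (SD 0.0932). Over all 14476 genes replicates 1, 2 and 3 lay at 0.113, 0.751 and −0.08, and what makes replicate 2 resemble the mutant stays open, as no biological explanation was tested.

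Photosystem genes were higher in wild-type callus replicate 1 than in the other wild-type calli, by a median of 1.97 log2 units. Green leaf tissue in the library would bring the stromal genes of photosynthesis at the same share of their leaf level, but their median was at most 0.352 of that prediction (10 genes, upper quartile 0.402), with RBCS1A, RCA and GAPA measured at 0.00608, 0.365 and 0.831 and the other 7 genes missing from the table and set at the highest value this allows, 3 RPKM, at a photosystem share of 0.465% of leaf over 31 genes. Scaling of the library would raise the other genes too, and the 16669 genes outside the list deviated by a median of −0.00458. Both explanations are argued against as the whole cause. No biological explanation was tested.

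EMF2 in leaf replicate 3 was 5.12 times the mean of the other leaf libraries, a ratio that 1.02% of the 16694 leaf genes reach. Reads from neighbours are argued against, since 0 bases of EMF2 overlap another gene and the flanking genes AT5G51220 and AT5G51260 were at 0.710 and 0.550 of the other leaf libraries. A scaling of the library is argued against by the median ratio of 0.920 over genes. The place of the genes that pass between the calli was also tested: of 680 genes within 2 Mb of EMF2, 6 of the 77 that passed lay there (AGL71, AGL72, AT5G56240, HAP8, SPL13A and SPL13B) against 3.05 by chance (one-sided Fisher's exact test, adjusted p = 0.0845). Variants linked to the emf2 lesion stay open for these 6 genes, since with 3.05 expected the test could miss a few linked genes. All 6 lie in near pairs: AGL71 with AGL72, SPL13A with SPL13B, and HAP8 (AT5G56250) with AT5G56240. The test counts the members of a pair as separate genes.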
